A study of Homo sapiens with 2 samples.

How the data were processed

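Gene expression was measured in HCCLM3 cells, an established human hepatocellular carcinoma line, after transfection with a small interfering RNA (siRNA) against CTHRC1 or with a scrambled siRNA. Each group had 1 sample, so there were 2 arrays in all. Per the labels' protocols, the cells were grown in DMEM with fetal calf serum, total RNA was extracted with Trizol, and biotinylated cRNA was made from 500 ng of it by the Affymetrix 3′ in vitro transcription method. This method primes from the poly(A) tail, so a probe set reads the 3′ end of a transcript. The array was the Affymetrix Human Genome U133 Plus 2.0 Array, per the file headers, and 54613 probe sets were given.

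The deposited signal intensities are on a linear scale, per the file headers one Signal per probe set and array with the word scaling. The 2% trimmed mean was 497.39 on the scramble array and 497.26 on the CTHRC1 siRNA array, so each array had been scaled as a whole to nearly the same level. The deposited table also gives, per array, a detection call (present, marginal or absent) with a detection p-value. For the pair of arrays the authors deposited a log2 signal log ratio with a low and a high bound, a change call (increase, marginal increase, no change, marginal decrease or decrease) and a change p-value. These columns are of the kind that the Affymetrix statistical algorithm (MAS5) writes from the probe pairs of a probe set. Per the submitters' processing notes, Partek 6.4 and RMA were used, but the deposited values are not RMA log2 values. The design had assumed RMA values, so log2 of the deposited intensity was taken here. A second table of the series held the same signal intensity for all 54613 probe sets. The software that wrote the Signal and change columns is not given in the sources used here, and probe sequences were not used here. A further 6 columns of probe pair numbers were not used.

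Probe sets were named through the Entrez Gene identifier in the file: 39925 had 1 gene, 1522 had several and 13166 had none. Of those with 1 gene, 38545 matched the current RefSeq gene table (used for names only, since its assembly differs from NCBI Build 36.1 (hg18), on which the file's positions lie), and 7383 took a newer symbol. Probe sets with several genes or none were left out of the gene comparisons. Names ending in _s_at or _x_at mark probe sets that can match several transcripts or cross-hybridise. The 3′ ends of close paralogues cannot be told apart with certainty on this array.

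All comparisons are log2 of the CTHRC1 siRNA signal minus log2 of the scramble signal. Each gene was represented by its probe set with the highest mean log2 signal over both arrays, kept if that mean was at or above the 50th percentile of all probe sets, a signal of 76.9. This left 12477 of 19761 genes, of which 10274 were called present on both arrays. With 1 sample per group no test of the conditions is possible and no p-value is given. A fixed size of 2-fold was used in its place. The authors' bounds and change calls compare the probe pairs of these 2 arrays, not the conditions, and hold no variation between cultures. Where a gene was called present only on the brighter array, the fold is given as at least a value. That value was computed against the dimmer signal or the lowest signal called present on that array (25.4 for scramble, 16.7 for CTHRC1 siRNA), whichever was higher. It is a limit by signal and not a minimum of the true change. For some of these genes, such as EGR2, DACT3 and SLC1A7, both of the authors' bounds were smaller in size than this value. Where neither array had a present call, no fold is given.

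The 29 gene lists, the size rule and the rule for named genes were fixed before the data were examined. A list with at least 5 measured members was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, drawn with replacement and matched on deciles of mean signal. A list stood apart if the percentile was under 2.5 or over 97.5. Genes of a pathway vary together, so such lists leave the random range more often than independent genes would, and the percentile describes these 2 arrays only. The named genes were CTHRC1, the 12 genes with the largest increase and the 12 with the largest decrease whose other kept probe sets all differed in the same direction, and up to 4 members per list with the largest absolute difference. After the values were seen, 15 genes per direction were added that had a present call on the brighter array, a 2-fold difference by both measures, the matching change call and no kept probe set in the other direction, as were list members with an increase or decrease call.

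On simulated data run on 12477 genes, with a spread taken from the differences between these same 2 arrays so that it gives no chance level for the observed counts, the size rule recovered 91.0% of genes with a true log2 change of 1.5 and 100.0% of those with 2.5. It also took 3.7% of genes without a change over all signal deciles, and 0.0% (to 1 decimal) of those in the upper 5 signal deciles. Of 100 simulated lists of 30 genes per setting, 4.0% stood apart without a shift, 76.0% with a planted shift of 0.2 and 96.0% with one of -0.3. The alternatives were other rules for the probe set, the filter and the fold, median centring, quantile and loess normalization, the second deposited table, unmatched random lists, list means and, added after seeing the data, detection calls, the authors' log ratio and change calls, leaving out _s_at and _x_at probe sets, and random lists matched on gene span as well. Gene span here is the aligned span of the probe set that represents the gene. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Some genes and 1 gene list are not reported here. Precision is limited by the number of arrays.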

Results

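Gene expression was compared between 2 cultures of HCCLM3, an established human hepatocellular carcinoma cell line. One had been transfected with a small interfering RNA (siRNA) against CTHRC1, which encodes a secreted glycoprotein with a short collagen-like repeat, and the other with a scrambled control siRNA. Each group had 1 sample on 1 array, so no value below has a replicate error, and a difference describes these 2 arrays. The arrays gave signals for 54613 probe sets. On the scramble array 23099 probe sets (42.3%) were called present and the median signal was 82.4. On the CTHRC1 siRNA array 24368 (44.6%) were called present and the median signal was 85.3. After dim probe sets were removed, 12477 genes were compared. Their log2 signals correlated across genes with a Pearson r of 0.978, where genes are not independent replicates, and 85.6% of them differed by less than 1.5-fold.

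The first comparison asked whether the targeted transcript differed as the labels state. CTHRC1 (Entrez Gene 115908) was read by 1 kept probe set, whose target aligns to the plus strand of chromosome 8 at 104452907 to 104464397 in the hg18 assembly of the file. Its signal was 431.3 on the scramble array and 191.1 on the CTHRC1 siRNA array, with a present call on both, which was 2.26-fold lower. In the authors' deposited table its signal log ratio was -1.4, with bounds of -2.0 and -0.8, and the change was called a decrease. The position of the siRNA target within the transcript was not given in the sources used here.

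The second comparison asked which other genes differed after CTHRC1 knockdown. By signal, SOST, which encodes the secreted Wnt antagonist sclerostin, had the largest increase among genes whose kept probe sets all went the same way. In the authors' deposited table the signal log ratios of FLJ13769 (2.8) and EDA (2.5), also called increased, were above that of SOST (2.2). Serpins of clade B and the urokinase receptor gene PLAUR were among the brightest genes that were lower by over 2-fold. By the 2-fold size rule 234 genes were higher and 220 were lower on the CTHRC1 siRNA array, so 51.5% of these 454 genes were higher. They were 3.6% of the genes compared, and without replicates there is no chance level to set this share against. In the upper 5 signal deciles 28 of 6238 genes passed. After quantile normalization 185 were higher and 270 lower, a higher share of 40.7%, and with the present call required on both arrays it was 64.0%, so the balance of directions depended on these choices. Of the 454 genes, 190 were called present on both arrays, 123 of them higher and 67 lower. A further 164 had no present call on either array, and 71.6% of the 454 lay in the 2 dimmest signal deciles. The robust SD of the log2 difference was 0.72 in the dimmest decile and 0.19 in the brightest. Of the higher genes, 78 were also called increased in the authors' deposited table, and of the lower genes, 44 were also called decreased.

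**Figure D1:**
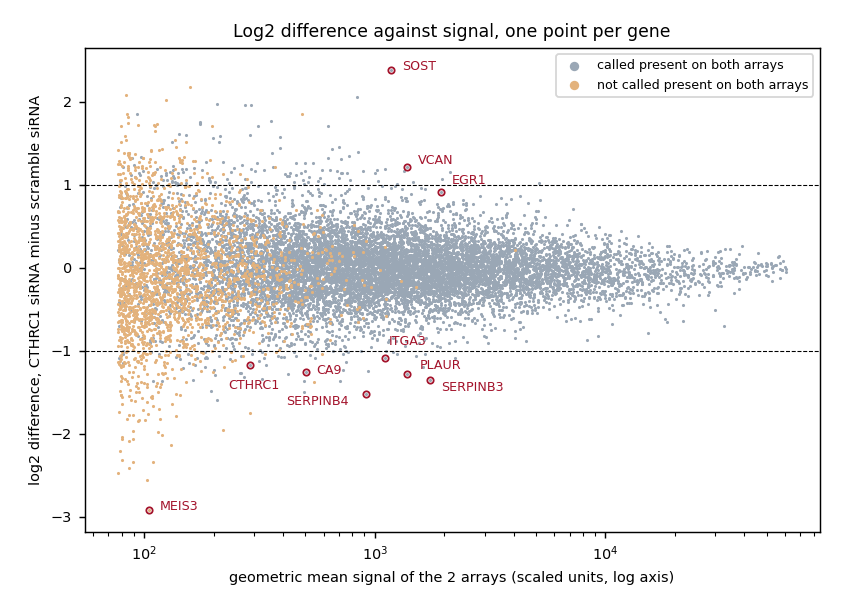
Log2 difference (CTHRC1 siRNA minus scramble siRNA) against the geometric mean signal of the 2 arrays in scaled units on a log axis, with 1 point per gene, dashed lines at 2-fold and circles at genes named in the text. The spread narrows from a robust SD of 0.72 in the dimmest decile to 0.19 in the brightest, and SOST lies above the 2-fold line while CTHRC1, PLAUR, SERPINB3 and SERPINB4 lie below it.

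Among the 12 largest increases, 6 genes were called present on both arrays. SOST (Entrez Gene 50964, minus strand of chromosome 17, 39186632 to 39191672 in hg18) had a signal of 515.4 on the scramble array and 2692.9 on the CTHRC1 siRNA array. Its difference was 2.39 on the log2 scale, and the authors' deposited table gave a signal log ratio of 2.2 with bounds of 1.9 and 2.5. The transcript DKFZp547E087 went from 409.3 to 1704.8, but its 3 probe sets differed by 0.18 to 2.06 on the log2 scale. ZNF721, a zinc finger gene, was 3.92-fold higher, hCG_1776259 and KIAA0485 were each 3.89-fold higher, and LOC390933 was 3.62-fold higher. Signal log ratios in the authors' deposited table were lower than these folds for ZNF721 (1.3), KIAA0485 (1.4) and LOC390933 (1.2, called unchanged). For genes called present only on the CTHRC1 siRNA array the fold is a limit by signal, not a minimum of the true change. By this limit EGR2, an immediate-early transcription factor, was at least 4.52-fold higher. FLJ13769 was at least 4.07-fold and EDA, the TNF-family ligand ectodysplasin A, at least 3.52-fold higher. In the authors' deposited table EGR2 was called unchanged, with a signal log ratio of 0.5 and bounds of -0.4 and 1.5. KLC3 (signals of 40.7 and 172.3), CACNA1G (44.3 and 160.0) and CACNG4 (254.3 and 916.1) had no present call on either array. The authors' deposited table called 7 of these 12 genes increased.

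None of the 12 largest decreases was called present on both arrays, and the authors' deposited table called 0 of them decreased. DACT3 was at least 5.07-fold lower, LINC01667 at least 4.62-fold, the cardiac actin gene ACTC1 at least 4.27-fold and TUT1 at least 4.18-fold, each by signal and with a present call only on the scramble array. Signal log ratios in the authors' deposited table were -1.1 for DACT3 (bounds of -2.0 and -0.2) and -1.3 for ACTC1 (-2.2 and -0.3), both smaller in size than these folds, and -2.1 for LINC01667 and TUT1. The other 8 had no present call. Their signals on the scramble and CTHRC1 siRNA arrays were 289.1 and 38.1 for MEIS3, 248.8 and 42.2 for KEAP1, 181.8 and 32.8 for PADI2, and 198.1 and 37.1 for KCP. They were 201.7 and 39.9 for LINGO3, 179.4 and 35.9 for BORCS6, 275.1 and 62.5 for TMEM184A, and 163.4 and 39.1 for SPNS2.

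Because the size rule favoured dim genes, a second set was chosen after the values were seen, from genes with a present call on the brighter array, a 2-fold difference by both measures and a matching change call. This left 41 higher and 28 lower genes. Of the lower ones, SERPINB4 (1545.3 to 538.9) was 2.87-fold lower, SERPINB3 (2773.4 to 1085.3) differed by -1.35 on the log2 scale, and SERPINB2 (788.7 to 305.9), which encodes an inhibitor of urokinase, was 2.58-fold lower. SERPINB3 and SERPINB4 are near-identical neighbours and their values are uncertain as separate measurements. PLAUR (2153.0 to 885.9) was 2.43-fold lower, and its 3 probe sets differed by -1.5 to -0.92. The authors' deposited table gave signal log ratios of -1.4 for SERPINB4, -1.3 for SERPINB3, -1.0 for SERPINB2 and -1.4 for PLAUR. The keratin gene KRT15 was 2.44-fold lower, DUOX2, an NADPH oxidase that makes hydrogen peroxide, 2.41-fold, and IQSEC2 2.58-fold. By signal, SLC1A7, a glutamate transporter gene, was at least 3.88-fold lower, the sulfotransferase gene SULT1B1 at least 3.61-fold and CLRN3 at least 3.13-fold. Their signal log ratios in the authors' deposited table were smaller in size than these folds. They were -1.2 for SLC1A7 (bounds of -1.7 and -0.6), -1.4 for SULT1B1 and -1.5 for CLRN3. On the higher side, the non-coding transcript DLEU2 (192.4 to 657.5) was 3.42-fold higher and SLC7A2, a transporter of cationic amino acids, at least 3.27-fold. The authors' deposited table gave signal log ratios of 1.7 for DLEU2 and 1.3 for SLC7A2. DLEU2 was read by an _x_at probe set, which can cross-hybridise. EIF3C (2.97-fold), ZNF138 (3.26-fold) and GUSBP1 (log2 difference of 1.70) were also higher, but share sequence with related copies and are uncertain.

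The third comparison asked whether gene groups fixed before the data were examined differed together. Of 29 lists, 27 had enough measured members. Of these, 9 had a median below and 2 a median above the range of random lists of like signal, where 1.35 would be expected by chance if genes varied independently. Genes of a pathway do not vary independently, so these percentiles describe the 2 arrays and carry no replicate check. Among lists inside the random range, the medians of the Wnt, ribosomal protein, epithelial, mesenchymal, NRF2 and p53 lists changed sign under median centring, quantile or loess normalization. List members other than the 4 with the largest difference are named below because the authors called them changed, and were chosen after their values were seen. Folds of list members are by signal, and members that the authors' deposited table called unchanged are named as such where its signal log ratio was under 0.5 of the log2 difference or its bounds included 0.

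**Figure D2:**
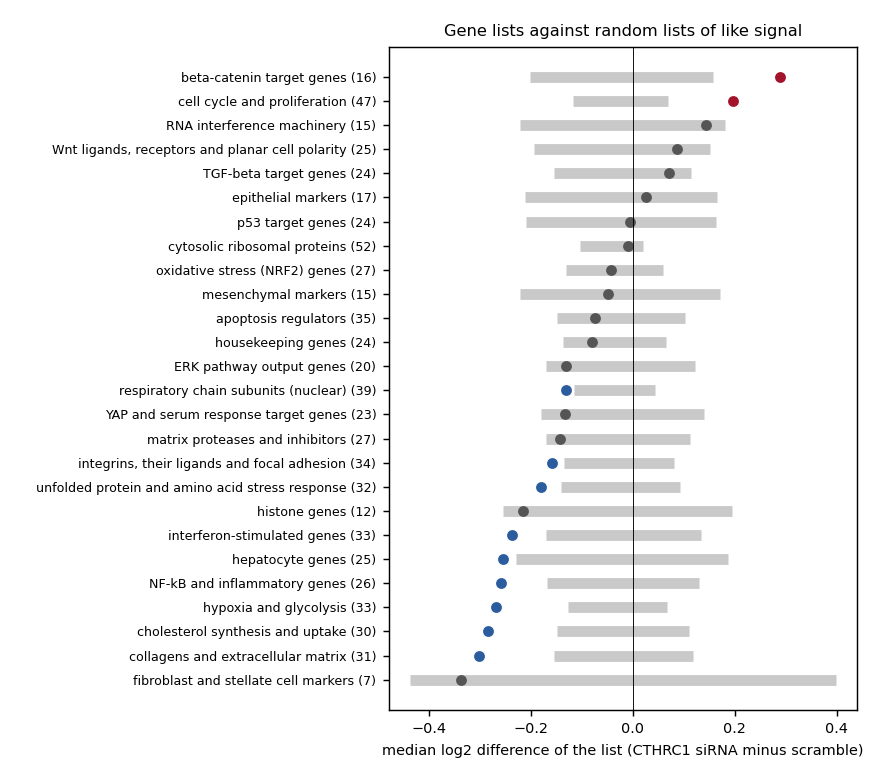
Median log2 difference (CTHRC1 siRNA minus scramble siRNA) of 26 of the 27 scored gene lists, with the number of measured members in brackets and a grey bar for the central 95% of 10000 random lists. Blue points (9 lists) lie below and red points (2 lists) above the bar, and the cytosolic ribosomal protein list lies at -0.01, inside it (0.05 after loess normalization).

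Hypoxia and glycolysis genes were lower as a group. Of 33 measured members 27 were lower, the median was -0.27 and it lay below all 10000 random lists. The authors' deposited table called 15 decreased and 1, EGLN1, increased. CA9, a carbonic anhydrase, went from 778.3 to 324.5 (2.40-fold lower), and ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, went from 1116.2 to 473.0 (2.36-fold lower). ANKRD37 was 1.92-fold and the aldolase gene ALDOC 1.81-fold lower. Further members that the authors' deposited table called decreased were the hexokinase gene HK1 (1.68-fold by signal), NDRG1 (1.60-fold), the glucose transporter gene SLC2A1 (1.34-fold) and the glycolytic genes PKM and LDHA, which differed by -0.32 and -0.30 on the log2 scale.

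Collagens and other extracellular matrix genes were also lower as a group, with 23 of 31 measured members lower and a median of -0.30, below all 10000 random lists. The authors' deposited table called 8 of them decreased and 3 increased. The type IV collagen gene COL4A2 was 2.19-fold lower and the proteoglycan gene DCN 1.90-fold lower. VCAN, which encodes the proteoglycan versican, went the other way: it was 2.31-fold higher, and its 5 probe sets differed by 1.14 to 1.33. THBS1 was 1.94-fold higher by its brightest probe set, while its 4 probe sets ranged from -1.31 to 0.96. Without probe sets that can match several transcripts, the list had a median of -0.20 at percentile 6.06 and no longer stood apart.

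Integrins, their ligands and focal adhesion genes had a median of -0.16 at percentile 0.75, with 23 of 34 members lower. The integrin genes ITGA3 (1619.0 to 761.6, 2.13-fold), ITGA5 (1.60-fold) and ITGA2 (1.58-fold) and the laminin gene LAMB3 (2.02-fold) were lower, and the authors' deposited table called each of them decreased. LAMA4 was 1.93-fold higher by its brightest probe set, while its 3 probe sets ranged from -1.15 to 0.95. Without probe sets that can match several transcripts the list median was 0.005, so its direction was not kept. The list stood apart in 12 of 15 other settings. It also lost this with the mean of all probe sets of a gene (percentile 2.75) and with unmatched random lists.

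Matrix proteases and their inhibitors did not stand apart, with a median of -0.14 at percentile 5.99, although 7 of 27 members were called decreased and 0 increased in the authors' deposited table. Besides PLAUR and SERPINB2, ADAMTS1 was 1.87-fold and the plasminogen activator gene PLAT 1.80-fold lower, followed by TIMP1, an inhibitor of metalloproteinases, and the collagenase gene MMP1, with differences of -0.65 and -0.63 on the log2 scale. Of these, ADAMTS1 was called unchanged in the authors' deposited table, with a signal log ratio of -0.9 (bounds of -1.7 and -0.1). SPINT1 had no present call, with signals of 258.1 and 126.3. With the mean in place of the median and under 4 other settings this list did stand apart.

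Inflammatory genes were lower. The NF-kB and inflammatory list had a median of -0.26 at percentile 0.11, with 18 of 26 members lower and 7 called decreased against 0 increased in the authors' deposited table. BIRC3, an inhibitor of apoptosis, went from 2190.2 to 1049.8 (2.09-fold lower) and IL32 was 1.92-fold lower. IL6 was at least 2.24-fold lower. The interleukin genes IL1B (1.52-fold) and IL1A (2.41-fold) were lower, but the second probe set of IL1A was higher by 0.64. Interferon-stimulated genes had a median of -0.24 at percentile 0.22, with 23 of 33 members lower, and the authors' deposited table called 7 decreased and 0 increased. IRF7, a transcription factor of the interferon response, was 2.10-fold lower, OASL 1.81-fold, IRF9 1.80-fold and IFI27 1.65-fold. The authors' deposited table called IRF7 and IL6 unchanged, with signal log ratios of -0.8 and -1.0.

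Of the metabolic lists, cholesterol synthesis and uptake had a median of -0.28 at percentile 0.01, with 22 of 30 members lower and 9 called decreased in the authors' deposited table. ACAT2 was 1.87-fold lower, the fatty acid desaturase gene FADS2 and the sterol carrier gene STARD4 were each 1.70-fold lower, and TM7SF2 was at least 1.75-fold lower. The authors' deposited table called ACAT2 and STARD4 unchanged, with signal log ratios of -0.3 (bounds of -0.7 and 0.0) and -0.5 (-1.2 and 0.2). The direction was lost without probe sets that can match several transcripts, where 17 members remained with a median of 0.06. Nuclear genes of the respiratory chain had a small median difference of -0.13 at percentile 0.87, with 29 of 39 members lower. NDUFA9 (1.28-fold), COX8A (1.27-fold), NDUFA1 (1.27-fold) and UQCRH (1.25-fold) differed most, and the list stood apart in 9 of 15 other settings. NDUFA9 was called unchanged in the authors' deposited table, with a signal log ratio of -0.1.

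Hepatocyte genes had a median of -0.25 at percentile 1.47, with 17 of 25 members lower, but stood apart in only 7 of 15 other settings. SERPINA1, which encodes alpha-1-antitrypsin, was at least 2.61-fold lower and TM4SF5 was 1.95-fold lower, while the fibrinogen gene FGG was 1.86-fold higher. HPX had no present call, with signals of 254.3 and 73.9. Albumin (ALB) was 1.25-fold lower. The unfolded protein and amino acid stress list had a median of -0.18 at percentile 0.42, with 22 of 32 members lower. It no longer stood apart with the mean (-0.10, percentile 8.3) or with the signal log ratio of the authors' deposited table (median -0.10, percentile 10.4). Of the 4 members with the largest difference 3 were higher: the stress transcription factor gene DDIT3 was 1.68-fold higher, and the amino acid synthesis genes ASNS and PSAT1 were higher by 0.61 on the log2 scale. CHAC1 had no present call, with signals of 149.3 and 69.2.

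**Figure D3:**
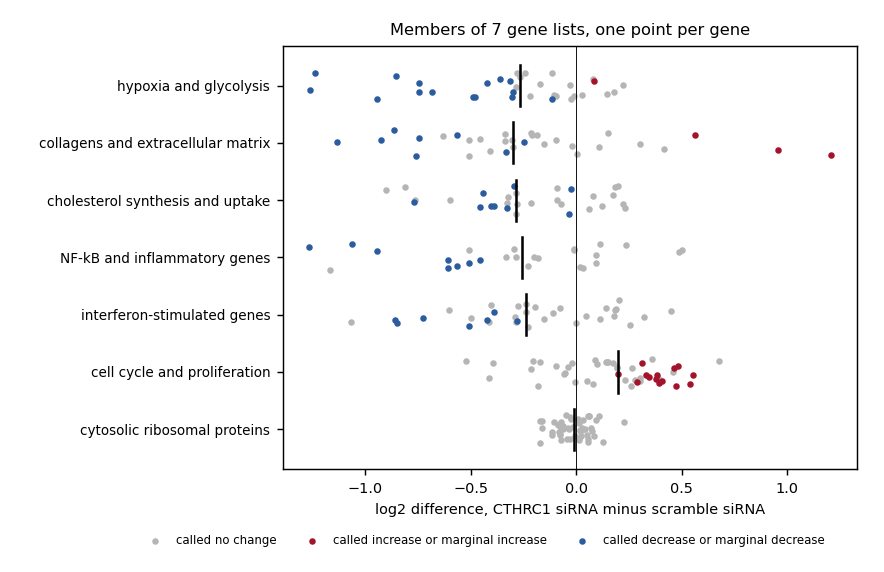
Log2 difference (CTHRC1 siRNA minus scramble siRNA) of each measured member of 7 gene lists, with 1 point per gene, black lines at list medians and colours for the authors' change calls. Hypoxia and glycolysis members lie mostly below 0 around a median of -0.27, cell cycle members mostly above 0 around 0.20, and ribosomal protein members close to 0.

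Cell cycle genes were higher as a group, with 34 of 47 measured members higher and a median of 0.20 that lay above all 10000 random lists. Of these members, 14 were called increased and 0 decreased in the authors' deposited table. The mitotic kinesin gene KIF23 was 1.60-fold higher, CCNE2, which encodes a cyclin of the G1 to S transition, 1.47-fold, and the spindle gene ASPM 1.45-fold, although the 3 probe sets of ASPM ranged from -0.41 to 1.19. CENPF (1.4-fold), MCM10 (1.39-fold) and NUSAP1 (1.38-fold) were higher as well. CCNE1 was 1.43-fold lower. The authors' deposited table called KIF23 and CCNE1 unchanged, with signal log ratios of 0.3 (bounds of 0.1 and 0.5) and -0.1 (-0.5 and 0.3).

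Beta-catenin target genes had a median of 0.29 at percentile 99.96, with 10 of 16 members higher, a mean of 0.13 and 3 members called increased in the authors' deposited table. These were MYC (6521.8 to 9357.6), AXIN2 (1.30-fold) and TCF7L2 (1.35-fold), and LGR5 was 1.43-fold higher. NKD2 (signals of 168.6 and 95.2) and BMP4 (225.1 and 307.7) had no present call. With the mean of all probe sets of a gene the list median was -0.01, so the direction depended on the probe set. The list stood apart in 11 of 15 other settings, and also lost this with the list mean (percentile 93.9), the median over a gene's probe sets (median 0.05, percentile 81.5) and no filter (median 0.13, percentile 94.5). Wnt ligands, receptors and planar cell polarity genes did not stand apart (median 0.09, percentile 89.3). The receptor gene ROR1 was 1.92-fold higher and DKK3 1.62-fold higher, and WNT6 (126.1 and 77.7) and WNT7B (213.6 and 139.2) had no present call.

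Lists of growth signalling genes did not stand apart, except that the TGF-beta list did so when all probe sets of a gene were averaged (median 0.13, percentile 98.8) or their median was taken (median 0.12, percentile 98.5). TGF-beta target genes had a median of 0.07 at percentile 91.4, while their mean was -0.01 at percentile 53.9. JUNB was 1.47-fold lower, and TGFB2 and TGFBR1 were 1.51-fold and 1.44-fold higher. YAP and serum response targets had a median of -0.13 at percentile 8.62, which was above 0 in 5 other settings (0.05 to 0.07), with EGR1 1.89-fold higher beside EGR2, and FOSL1 (1.66-fold) and DUSP1 (1.59-fold) lower. ERK output genes had a median of -0.13 at percentile 7.99, with EPHA2 1.56-fold lower and no present call for EPHA4 (127.3 and 79.8). JUNB was called unchanged in the authors' deposited table, with a signal log ratio of -0.2.

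Markers of epithelial and mesenchymal state went both ways. Epithelial markers had a median of 0.03 at percentile 70.2: CRB3 was 2.80-fold lower, while ESRP2 (2.07-fold), PKP2 (1.98-fold) and KRT7 (1.65-fold) were higher. Mesenchymal markers had a median of -0.05 at percentile 42.4. The transcription factor gene SNAI1 was 2.13-fold lower and SPARC 1.55-fold lower, ZEB2 was 1.35-fold higher, and ACTA2 had no present call (135.5 and 72.9). In the authors' deposited table CRB3, ESRP2, SNAI1, SPARC and ZEB2 were called unchanged, with signal log ratios of -0.9, 0.3, -0.2, -0.4 and 0.1.

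Of the remaining lists, p53 target genes had a median of -0.01 at percentile 57.1, while their mean was 0.02 at percentile 63.1. CDKN1A, an inhibitor of cyclin-dependent kinases, was 1.64-fold lower, as was BBC3, and TP53INP1 differed by -1.09 on the log2 scale. The authors' deposited table called BBC3 unchanged, with a signal log ratio of 0.0 (bounds of -0.4 and 0.3), and TP53INP1 too, with -0.6 (-1.6 and 0.3). PLK3 (104.6 and 187.4) and MDM2 (87.5 and 155.8) had no present call. Apoptosis regulators had a median of -0.07 at percentile 21.5, with BIK 1.81-fold and BCL2L1 1.46-fold lower. NRF2 genes of the oxidative stress response had a median of -0.04 at percentile 45.5, with SRXN1 1.34-fold lower and GCLC, OSGIN1 and ME1 between 1.25-fold and 1.29-fold higher. Histone genes had a median of -0.21 at percentile 5.25, just under 2.5 after loess normalization (2.49) or with present calls on both arrays (2.45), with H1-2 1.72-fold and H1-10 1.43-fold lower and H2BC9 1.52-fold higher. H2AC18 was at least 1.39-fold higher. BCL2L1, SRXN1, OSGIN1, H2BC9 and H2AC18 were called unchanged in the authors' deposited table, with signal log ratios of -0.3, -0.2, 0.0, 0.2 and -0.2.

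Ribosomal protein and housekeeping genes, included as references, lay inside the random range. Cytosolic ribosomal protein genes had a median of -0.01 at percentile 83.6, which was 0.05 after loess normalization, and 0 of 52 were called changed in the authors' deposited table. RPL23 and RPL3 were 1.13-fold lower and RPS19 was 1.12-fold lower, with signal log ratios of 0.0, -0.1 and 0.0 in the authors' deposited table. Housekeeping genes had a median of -0.08 at percentile 19.9 (0.08 without probe sets that can match several transcripts) and 0 of 24 called changed in the authors' deposited table, with TUBB 1.25-fold, RAB7A 1.21-fold and VCP 1.17-fold lower and GUSB 1.19-fold higher. RNA interference machinery had a median of 0.14 at percentile 94.7, and stood apart by its mean (0.22, percentile 98.9). TNRC6B (293.6 to 702.5) was 2.39-fold higher, with 7 probe sets between 0.29 and 1.26. That fold came from an _x_at probe set, which can cross-hybridise, and was the largest of the 7. The authors' deposited table gave TNRC6B a signal log ratio of 0.9 (bounds of 0.6 and 1.3). AGO1 was 1.64-fold higher, DICER1 1.42-fold higher and TARBP2 1.44-fold lower. TARBP2 was called unchanged in the authors' deposited table, with a signal log ratio of -0.3 (bounds of -0.5 and 0.0).

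Markers of other cell types were mostly below the signal filter. Of 15 fibroblast and stellate cell markers 7 were measured, with a median of -0.34 at percentile 6.05 (2.29 with unmatched random lists); besides DCN and ACTA2, COL3A1 went from 477.6 to 706.8 and RGS5 was 1.53-fold higher. Endothelial markers had 4 of 15 members measured (median -0.17) and leukocyte markers 3 of 20 (median -0.53), too few to be set against random lists. KDR was 1.63-fold lower, PECAM1 1.29-fold higher, ITGAM 1.16-fold lower and CD74 at least 1.44-fold lower. LYVE1 (194.5 and 61.3), FLT1 (80.3 and 141.5) and CORO1A (130.7 and 90.8) had no present call. RGS5, KDR, PECAM1 and CD74 were called unchanged in the authors' deposited table, with signal log ratios of 0.4, -0.5, 0.2 and -0.6 and bounds that included 0.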

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

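Of the tests given here, those of scaling by signal and of DNA for the part without strand were chosen only after the result was seen, and the others were set out before it.

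Probe sets that the annotation pairs with no gene were not used in any comparison of the report, but carried a signal in one direction. Of 3708 such probe sets bright enough to be kept, the authors' deposited table called 711 (19.2%, 95% Wilson interval 17.9% to 20.5%, counting error only) increased on the CTHRC1 siRNA array and 29 (0.78%) decreased. Of 22758 probe sets with 1 gene, it called 5.73% increased and 4.66% decreased. The median log2 difference was 0.32 for unnamed probe sets. Unnamed probe sets with 1 alignment were placed by the aligned span of the named genes' own probe sets. Inside the span of a named gene on its strand, 398 of 1473 were called increased. The counts were 53 of 471 on the opposite strand and 175 of 1430 outside named genes. These spans can be shorter than the genes, so the class outside may hold parts of genes.

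More unspliced RNA of genes on the CTHRC1 siRNA array is a candidate explanation: the share called increased was 15.77 percentage points higher on the same strand than on the opposite strand (95% interval 11.90 to 19.22). This interval and those below for such probe sets treat each probe set as independent and hold no variation between cultures. In the brightest of 5 bins of signal the shares were alike: 29.4% of 17 on the same strand, 28.6% of 28 on the opposite strand and 29.5% of 44 outside. In each other bin the same-strand share was the highest. Genomic DNA carried into the sample would raise all classes alike if it were labelled alike in each. The same-strand share was 14.78 points (11.93 to 17.60) above that outside named genes, which argues against such DNA as the whole cause. For the classes without that strand, unnamed probe sets exceeded named ones of like signal by 0.195 on the log2 scale (0.161 to 0.229). The labelling primes from poly(A), and how near each class lies to runs of A in DNA was not examined. This difference therefore cannot tell whether DNA was present, and DNA stays open for these classes. A scaling that depends on signal would shift named probe sets of like signal by the same amount, and the difference averaged 0.322 over 5 bins of signal, and the values of single bins ranged from 0.242 to 0.395. A bias by base composition, a difference in RNA processing or quality between the 2 extracts, and an effect of the siRNA stay open and untested, since each group had 1 sample.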

How the results depend on the processing

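The alternatives of detection calls, the authors' signal log ratio and change calls, probe sets without _s_at and _x_at, and random lists matched on gene span were chosen after seeing the data. No paired analysis was possible because each group had 1 sample. The CTHRC1 level was lower in every setting that gave it a value, with log2 differences of -1.263 to -1.168, and -1.4 in the authors' deposited table; the filter at the 75th percentile removed it. The second deposited table moved no value. The median of all genes moved by under 0.1 in each setting.

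The counts of genes past 2-fold, 234 higher and 220 lower, depended on the filter and threshold. They were 1955 and 2244 without a filter, 44 and 27 with the filter at the 75th percentile, and 128 and 72 with present calls on both arrays, where each gene's brightest such probe set was taken. They were 180 and 120 with a present call on at least 1 array, and 140 and 180 by the signal log ratio of the authors' deposited table, where 43.8% were higher in place of 51.5%. They were 843 and 950 at 1.5-fold, 31 and 37 at 3-fold, 729 and 621 by the change calls of the authors' deposited table alone, and 78 and 44 with both rules. Stricter rules give fewer genes by construction, and for the other counts the cause was not tested.

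Among lists that stood apart and genes past 2-fold, the direction reversed for beta-catenin targets with the mean of all probe sets (-0.012), and without _s_at and _x_at probe sets for the integrin list (0.005), the cholesterol list (0.055) and the gene IL1A (0.643). Leaving out those probe sets changes which probe set or how many genes are read; otherwise the cause was not tested. The hypoxia, NF-kB, interferon and cell cycle lists stood apart in all 15 settings. Median centring and the second deposited table cannot move a percentile. They therefore add nothing to the counts of 15 settings given here and above. Of 402 list values under alternatives, 332 kept their direction and side, 22 no longer stood apart, 11 newly did and 3 reversed. The other 34 were sign changes in 10 lists that did not stand apart, among them YAP targets in 5 settings (up to 0.070), Wnt genes in 5 (down to -0.063) and housekeeping genes in 1 (0.084). Of 2673 values of named genes, 2611 kept theirs, 19 fell short of 2-fold, 19 newly passed it, 23 under 2-fold changed sign and 1 past it reversed. Signal over background limits dim genes most: 325 of the 454 genes past 2-fold lay in the 2 dimmest deciles.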

Other observations

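Gene families and annotated processes not described above were examined after the data were seen. The 330 measured genes named ZNF, mostly zinc finger transcription factors, had a median of 0.18, above all 10000 random lists. The authors' deposited table called 52 of them increased and 3 decreased. ZNF721 and ZNF138 had already been seen among the increases, so this median is no independent evidence. Whether it shares a cause with the rise of unnamed probe sets was not tested. The 9 serpin clade B genes had a median of -0.52, with 5 called decreased and 0 increased in the authors' deposited table. This family was picked because SERPINB2, SERPINB3 and SERPINB4 had been seen among the decreases, so its median is no independent evidence, and SERPINB3 and SERPINB4 are hard to separate. Keratin genes (11, median 0.03), S100 genes (12, median -0.05), SRSF splicing factor genes (10, median 0.06) and small nucleolar RNA host genes (15, median -0.02) stayed inside the random range. The ZNF median was 0.118 to 0.185 and the serpin clade B median -0.569 to -0.512 under median centring, quantile and loess normalization, while the keratin median was -0.003 after quantile normalization.

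Of 420 annotated biological processes, 30 lay below and 18 above the random range, with 10.5 expected on each side if genes varied independently. Higher processes included mRNA transport (56 genes, median 0.12), DNA replication (121 genes, 0.10, percentile 99.98), chromatin modification (141 genes, 0.09, percentile 99.95) and DNA repair (207 genes, 0.07, percentile 99.99). Lower ones included blood coagulation (47 genes, median -0.19, percentile 0.23) and vesicle-mediated transport (176 genes, -0.11, percentile 0.14). The medians of these 6 processes kept their direction under the same 3 settings. Processes share genes with each other and with the lists of the report.

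Of the tests below, the matching on gene span and those that split the genes past 2-fold by present calls were chosen only after seeing the data. The lower level of hypoxia and glycolysis genes was set against explanations from the arrays. Under quantile and loess normalization the list median was still below 0, at -0.237 to -0.236, and its highest percentile was 0.0. Median centring moves all genes alike and tests nothing here. Quantile and loess normalization move genes of like signal nearly alike, and the random lists were matched on signal. This percentile could therefore hardly change, and it cannot decide on scaling between the arrays. With random lists matched on the aligned span of each gene's probe set as well, the percentile was also 0.0, which argues against a bias by that span. Such a span can be shorter than the gene, so the full span of the gene was not tested. An effect of the CTHRC1 siRNA and a difference between 2 single cultures, such as in density or oxygen, stay open, because the design has no replicate.

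Most genes past 2-fold were dim, so noise of dim probe sets was tested with each gene's second kept probe set. It went the same way in 65.4% of 104 genes (95% interval 55.8% to 73.8%, Wilson, counting error only). It was also past 2-fold that way in only 21 of them. The share argues against noise that is independent between probe sets as the whole cause in these 104 genes. Noise common to both probe sets of a gene could also give such a share, and was not tested. Of the 104 genes 73 were called present on both arrays, against 190 of all 454 genes past 2-fold, so the share says less about the dim ones. For genes called present on both arrays the share was 68.5% of 73 (57.1% to 78.0%). For the other 31 genes it was 58.1% (40.8% to 73.6%), and these cannot be told apart from noise, because so few have a second probe set.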
